A study of Mus musculus with 12 samples.

How the data were processed

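Splenic CD8 T cells of male mice were purified with an enrichment kit and profiled on Affymetrix mouse expression arrays. The mice carried a Cre recombinase driven by the Cd4 promoter together with either intact Scap genes (Cd4-Cre/Scap+/+ littermate controls, here WT) or floxed ones (Cd4-Cre/Scapfl/fl, here KO). Scap encodes the escort protein that brings SREBP transcription factors to the Golgi. Cells were taken quiescent (T0) or after 6 h on plates coated with antibody to CD3, with antibody to CD28 in solution (T6), which gave 4 groups of 3 arrays. PolyA RNA was extracted with a column kit and labelled with biotin.

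The deposited values are intensities: each is the linear signal intensity of a probe set made by the authors with the Affymetrix GCOS software, whose version is not stated. The labels do not say how background was removed or how probes were summarised. The mean signal between percentiles 2 and 98 was 500.003 on every array, so the values had been scaled per array. Medians per array lay between 61.3 and 76.2. For arrays, the number of arrays limits the precision.

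The table held 45101 probe sets, of which 64 were controls. Of the others, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none, and the first kind mapped to 18193 genes. Gene names and neighbourhood came from the mouse annotation of assembly GRCm38.p6. No coordinates are printed, because the files name no build for the probes. Signals were taken as log2(signal + 16) with no further normalization. The added 16 understates the changes of weakly detected genes. A gene was represented by its probe set with the highest mean, and was kept when that probe set lay above percentile 40 of its array on at least 3 of the 12 arrays. This left 13156 genes.

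Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a fit with a coefficient for each of the 4 groups over all 12 arrays. The contrasts were KO against WT at T0 and at T6, T6 against T0 in each genotype, and the difference between those changes (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors given with a log2 change are standard errors (SE) of that fit. Values of single arrays and marker lists were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 arrays is 0.1.

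Before the data were examined, 21 gene lists were fixed for sterol and fatty acid metabolism, LXR targets, T cell activation, naive and effector states, glycolysis, amino acid and one-carbon metabolism, ribosome biogenesis, cell cycle, stress, interferon response, apoptosis, T cell identity, sex, and markers of B cells, CD4 T cells, myeloid cells, NK cells and erythroid cells. The 20 lists with at least 3 tested members were tested in the 5 contrasts with limma's camera at a preset correlation of 0.01, adjusted over the 100 tests. Of these, 43 passed 0.05. With an estimated correlation 0 passed, and with fry 24 of the 43 did. Each list call in the text is therefore given with its adjusted p under an estimated correlation.

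The rule for named genes was also fixed in advance. For each contrast it takes Scap, up to 5 rises and 5 falls that are largest in log2 change among called genes whose groups do not overlap and whose higher group mean exceeds the median of tested genes (8.98), and up to 4 members of each list by smallest p. All members of the sterol and fatty acid lists may be named in KO against WT. With fewer than 3 called genes it takes the 3 with the smallest p. Genes named outside it are said to be so.

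The design text does not say which arrays share a mouse. After subtraction of group means, arrays of the same replicate number correlated across genes at 0.18, 0.46 and 0.38 between KO T0 and KO T6, and at 0.23, -0.06 and -0.11 between WT T0 and WT T6. Arrays of unlike number correlated at -0.40 to 0.14 in KO and at -0.16 to 0.23 in WT. In WT, T0 replicate 2 with T6 replicate 3 gave 0.20, and T0 replicate 3 with T6 replicate 2 gave 0.23. A block by replicate number may therefore not match mice in WT. Genes are not independent replicates. Whether arrays of a replicate number share a mouse is therefore not known, and the main test does not pair them. If they do, the tests of activation and of the interaction leave out a pairing. Values with a block for replicate number are given beside the lists whose call they change. Among the results for named genes this block added 10 calls and took away 7.

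The test was checked on simulated data with 200 changed genes among 13156. For KO against WT at T6 it recovered 10.4% of genes changed by 0.5, 58.2% of those changed by 1 and 89.4% of those changed by 2 on the log2 scale, with 4 false calls. For the interaction the shares were 2.99%, 43.3% and 81.8%, with 3 false calls. Each of the 3 set tests found all 3 shifted list tests and called 0 others. The simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes.

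Alternatives were another added constant (1 or 64), quantile normalization, median centring, no filter or one at percentile 60, the mean of a gene's probe sets, all probe sets tested separately, a mean-variance trend, separate fits, blocks by replicate, and leaving out each array. After the data had been seen, 3 more were added: leaving out chromosome 9 genes, a composition covariate (mean of the B cell and myeloid lists per array) and an RNA quality covariate (3' minus 5' signal of the Actb control probe sets). The cholesterol synthesis list was also fitted with the mean of the T cell identity list or of the erythroid list as a covariate. Marker lists for macrophages, dendritic cells, neutrophils, erythroid cells, B cells and plasma cells were also added then.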

Results

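Gene expression was measured on 12 arrays of mouse splenic CD8 T cells, 3 for each combination of genotype (WT or KO for Scap) and state (quiescent T0 or T6, after 6 h of activation). Across all probe sets, arrays of a group correlated at 0.969 to 0.978 and arrays of different groups at 0.949 to 0.976. The first principal component held 44.2% of the variance and separated T0 from T6. On the second component KO T6 replicate 2 lay apart, at -48.7. The Y-linked gene Eif2s3y lay between 11.40 and 11.64 and Xist between 5.46 and 6.39 as group means on the log2 scale, in samples labelled male. None of the 4 tested sex check genes was called in KO against WT. Xist was called higher in WT on activation (adjusted p = 0.046), at a level near background where no size is given, and the list was called in no contrast (lowest adjusted p = 0.879).

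The first question was how much Scap signal the KO cells held. The tested Scap probe set stood at 11.26 ± 0.25 in WT and 11.01 ± 0.23 in KO at T0, and at 11.57 ± 0.02 in WT and 11.10 ± 0.04 in KO at T6 (log2 signal, SD, n = 3). The log2 difference was -0.25 at T0 (SE 0.14, adjusted p = 0.593) and -0.47 at T6 (SE 0.14, adjusted p = 0.271), so neither was called. The other Scap probe set stood at 6.90 in WT and 6.78 in KO at T0, and at 7.19 in WT and 6.93 in KO at T6. The labels do not say which part of the gene was removed, and where the probes lie relative to it was not analysed here.

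The comparison of quiescent KO and WT cells asks how the genotypes differed before activation. In KO cells 5 genes fell and 0 rose. Insig1, which encodes an ER protein that holds the SCAP and SREBP complex back, fell by 0.78 (SE 0.10, adjusted p = 0.044), from 10.32 ± 0.15 to 9.54 ± 0.02 (log2 signal, SD, n = 3). This call was lost when any 1 of the 12 arrays was left out and was kept in 6 of 25 alternatives (adjusted p up to 0.249). The largest fall was that of Bace1, the beta-secretase, by 3.14 (SE 0.24, adjusted p = 0.0019). Its KO mean of 5.92 lay near background, so the size depends on the processing: over the alternatives it ranged from -1.87 to -3.51, and its other probe sets gave -1.16 to -1.66. Pxylp1, a phosphatase acting on xylose in proteoglycan linkers, fell by 1.94 and Tmem108 fell by 1.83, a call kept in 8 of 24 alternatives. Wscd2, which lies outside the rule and was chosen after its values were seen, fell by 1.02, a call kept in 12 of 25 (adjusted p up to 0.167). Bace1, Pxylp1 and Tmem108 lie on chromosome 9, as Scap does.

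Of the 17 measured cholesterol synthesis genes at T0, 16 had a negative log2 difference, 0 were called over all genes and 6 fell when adjusted over the list alone. The values nearest to a call were Sc5d at -1.06 (adjusted p = 0.051), Hsd17b7 at -0.67 and Sqle at -0.99, which encode a desaturase, a ketoreductase and squalene epoxidase. The list median was -0.27 and the list was called lower (camera adjusted p = 1.4e-06; adjusted p = 0.216 with an estimated correlation). Of the 11 measured genes of sterol uptake and SREBP regulation, 1 fell (Insig1), and 3 fell when adjusted over the list alone. Srebf2, which encodes the SREBP of sterol synthesis, stood at -0.60 and Srebf1 at -0.37. This list was called lower (median -0.14, adjusted p = 0.0012; adjusted p = 0.199 with an estimated correlation). Of 19 fatty acid synthesis genes 0 were called, with Acsl3 at -0.58, Scd1 at 1.37 and Fasn at -0.10. Their median was -0.05, their mean 0.0058 and the test pointed down (adjusted p = 0.524), so these differ in sign.

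Markers of other cells also differed between the quiescent genotypes. All 13 B cell markers were higher in KO, with a median of 0.62 and Ms4a1 at 2.15, and the list was called higher (adjusted p = 4.3e-05; adjusted p = 0.448 with an estimated correlation). All 13 myeloid markers were higher, with a median of 0.50 (adjusted p = 4.8e-05; adjusted p = 0.366 with an estimated correlation). The 3 erythroid markers had a median of 2.32 (adjusted p = 0.011; adjusted p = 0.366 with an estimated correlation), and without KO T0 replicate 2 the call was lost (adjusted p = 0.0552). All 11 T cell identity genes were lower, with a median of -0.23 and Cd3e, on chromosome 9, at -0.83 (adjusted p = 3.0e-04; adjusted p = 0.448 with an estimated correlation). The chromosomes of the other identity genes are not given here, so Cd3e need not be the only one on chromosome 9. Naive T cell and quiescence genes had a median of -0.18 (adjusted p = 0.0012; adjusted p = 0.366 with an estimated correlation), with Ccr7 and Klf2 each at -0.48. Cell cycle genes had a median of 0.41 (adjusted p = 4.3e-05; adjusted p = 0.586 with an estimated correlation). Early T cell activation genes had a median of 0.18 (adjusted p = 0.042; adjusted p = 0.677 with an estimated correlation), and this call was lost without WT T0 replicate 2 (0.0766), WT T0 replicate 3 (0.304), WT T6 replicate 1 (0.0518), WT T6 replicate 2 (0.0521), WT T6 replicate 3 (0.0584) or KO T0 replicate 3 (0.336). It was also lost with log2(signal + 64) (0.0502), with the mean of a gene's probe sets (median 0.09, adjusted p = 0.141) and in a separate fit (0.0820). Interferon response genes had a median of -0.28 (adjusted p = 0.0082; adjusted p = 0.661 with an estimated correlation), and this call was lost without WT T0 replicate 2 (0.135) or KO T0 replicate 1 (0.0776). No member of these 8 lists was called over all genes, and adjusted over the list alone 1 T cell identity gene fell and 1 erythroid marker rose.

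In the T0 comparison 1286 genes had an unadjusted p under 0.05, where chance gives 658. The count of 5 fell to 2 without WT T0 replicate 1, WT T6 replicate 3, KO T6 replicate 3 or any of the 3 KO T0 replicates and to 3 without WT T0 replicate 3, KO T6 replicate 1 or KO T6 replicate 2, and was 9 without WT T0 replicate 2. Other processing gave 1 to 10, and with chromosome 9 genes left out 0 genes were called, where Insig1 and Wscd2, which lie on chromosome 5, kept their values (-0.78 and -1.02) with adjusted p = 0.0955 and 0.0671.

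After 6 h of activation, the comparison of KO with WT asks how the genotypes differed once activated. In KO cells 9 genes fell and 4 rose. Of the 9, 5 belong to the sterol pathway. Cyp51, lanosterol demethylase, fell by 1.75 (SE 0.18, adjusted p = 0.0064), from 10.36 ± 0.10 to 8.61 ± 0.34 (log2 signal, SD, n = 3), which is 3.37-fold. Sc5d fell by 1.59 (SE 0.14, adjusted p = 0.0040; -0.72 and -0.52 on its other probe sets and -0.94 for the mean of all), Idi1, isopentenyl diphosphate isomerase, fell by 1.43, Insig1 fell by 1.15 and Hmgcs1, HMG-CoA synthase, fell by 0.92. Over the alternatives the call was kept in 21 of 25 for Cyp51, 21 of 24 for Sc5d, 22 of 25 for Insig1, 13 of 25 for Hmgcs1 and 6 of 25 for Idi1 (adjusted p up to 0.513). Tyrobp, an adaptor of myeloid and NK cell receptors, rose by 1.68 (SE 0.25, adjusted p = 0.048), a call kept in 6 of 25. The other called genes lie outside the rule and were chosen after their values were seen: Vcam1 rose by 1.13 (kept in 6 of 25) and Mast4 by 0.73 (0 of 23), and Zc3h13 (20 of 25), Pxylp1 (8 of 24), Mir1949 (5 of 25) and 9230112J17Rik (2 of 22) fell. Zc3h13 stood at -0.90 on its tested probe set and at -0.96 and -0.07 on its others, so its probe sets disagree. Tlr4 was called higher, but its WT mean of 4.23 lies below the filter level, so no size is given.

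**Figure D1:**
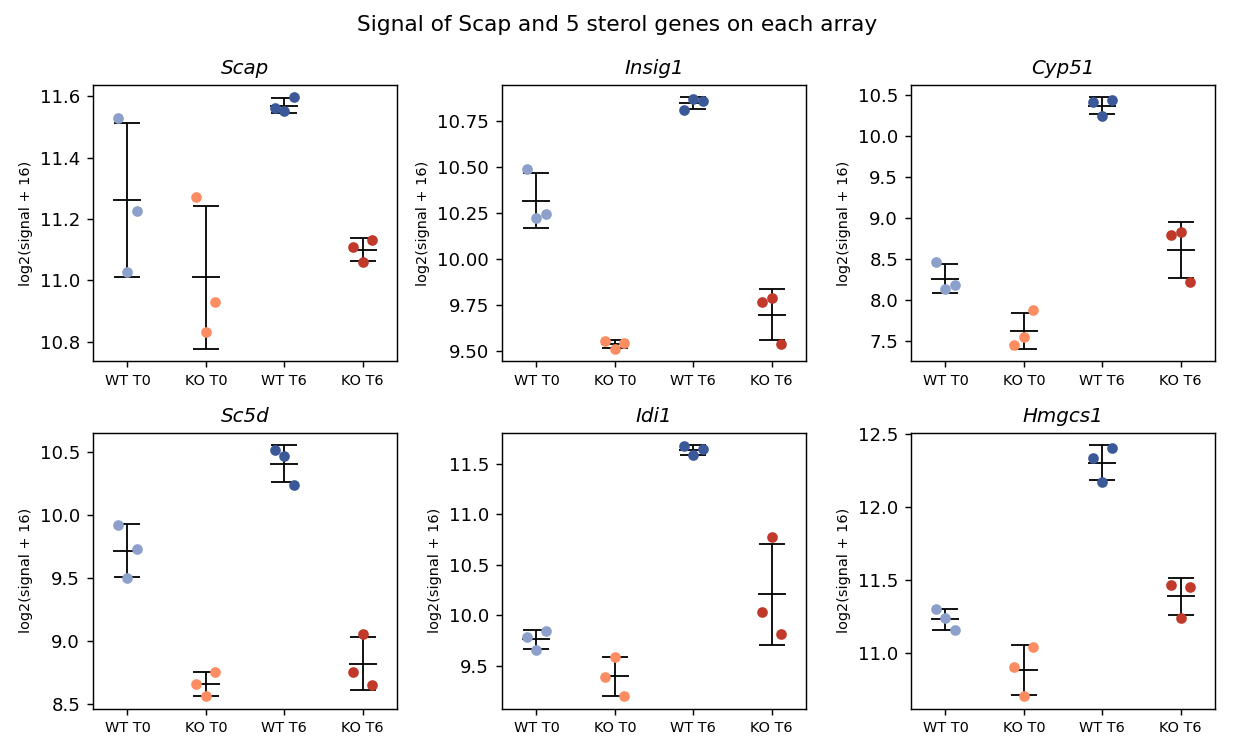
Signal of Scap and 5 sterol genes on each array. The vertical axis of each panel is log2(signal + 16), points are arrays, long bars are group means and whiskers are 1 SD (n = 3); at T6 every KO array lies below every WT array for all 6 genes.

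All 17 measured cholesterol synthesis genes had a negative log2 difference at T6. Of these, 4 fell (Cyp51, Sc5d, Idi1 and Hmgcs1), 13 did not pass the test, and 10 fell when adjusted over the list alone. Sqle stood at -1.30, Msmo1 at -0.85 and Hsd17b7 at -0.82. The list median was -0.62 and the list was called lower (camera adjusted p = 2.6e-16; adjusted p = 0.0676 with an estimated correlation). Sc5d lies on chromosome 9, and with chromosome 9 genes left out the median was -0.55. Of 11 sterol uptake and regulation genes 1 fell (Insig1), and 3 fell when adjusted over the list alone (Insig1, Srebf2 at -0.81 and Srebf1 at -0.40). Tmem97, at -0.65, did not pass there (limma adjusted p = 0.0806). The list was called lower (median -0.20, adjusted p = 2.3e-05; adjusted p = 0.0676 with an estimated correlation). Of 19 fatty acid synthesis genes 0 were called over all genes and 1 (Aacs, at -0.39) when adjusted over the list alone. Fasn stood at -0.25, Acss2 at 0.48 and Scd1 at 1.49. The median was 0.05 and the mean 0.09, while the test pointed down (adjusted p = 0.344). None of the 10 LXR target genes was called in either KO against WT comparison, with Apoe at 0.71 at T0 and 0.51 at T6 (list adjusted p = 0.951 and 0.859).

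**Figure D2:**
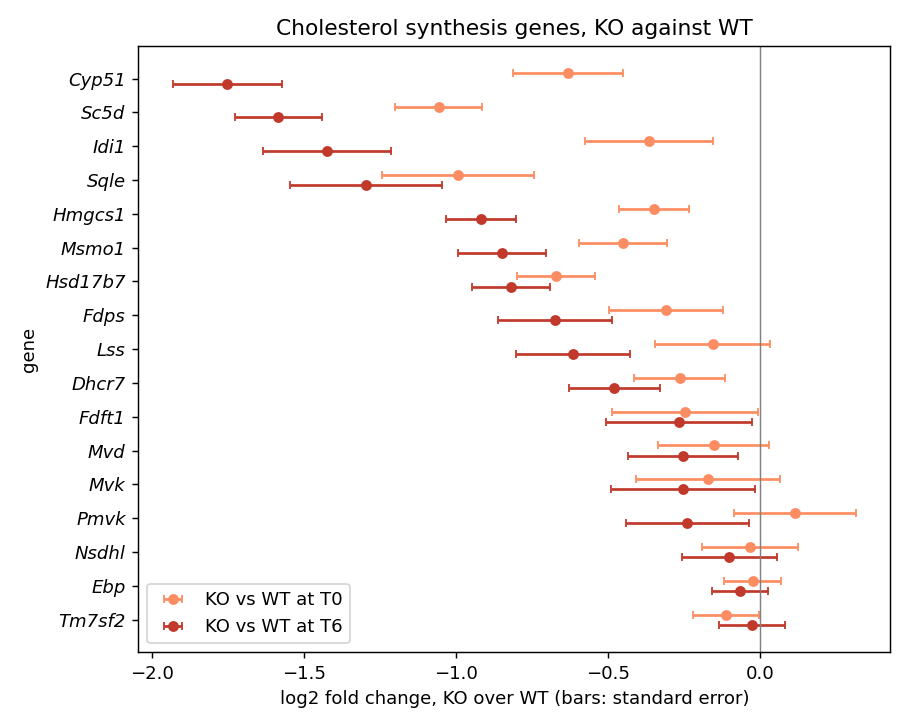
Log2 fold change of KO over WT for the 17 measured cholesterol synthesis genes at T0 and T6. The horizontal axis is log2 fold change and bars are standard errors of the limma fit; 16 of 17 values lie below 0 at T0 and 17 of 17 at T6.

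Ribosome biogenesis genes were lower in KO in 19 of 20 cases, with a median of -0.14 and Nop58 at -0.55 (adjusted p = 5.0e-07; adjusted p = 0.366 with an estimated correlation). Amino acid transport and one-carbon genes had a median of -0.11 (adjusted p = 0.031; adjusted p = 0.448 with an estimated correlation), and the call was lost without WT T6 replicate 1 (0.328) or KO T6 replicate 2 (0.0506), with quantile normalization (0.0952) and with the filter at percentile 60 (0.0545). Naive T cell and quiescence genes had a median of -0.20 (adjusted p = 0.0026; adjusted p = 0.408 with an estimated correlation). Cell cycle genes had a median of 0.50 (adjusted p = 0.0024; adjusted p = 0.661 with an estimated correlation), and the call was lost without WT T6 replicate 1 (0.0599) or KO T6 replicate 2 (0.561). The cell cycle mean was 11.72 on KO T6 replicate 2 and 10.61 on each of the other KO T6 arrays, and the erythroid marker mean was 13.48 there against 11.69 and 9.90. At T0 the highest means of both lists were on KO T0 replicate 2, at 11.69 and 13.22. Early activation genes had a median of 0.03 while their test pointed down (adjusted p = 0.323). Glycolysis (0.353), ER stress (0.951), interferon response (0.344), effector and memory genes (0.549) and apoptosis genes (0.146) were not called at T6 by these adjusted p. No gene of the lists in this paragraph was called over all genes at T6, while adjusted over the list alone 1 ribosome biogenesis gene and 1 early activation gene fell, 1 glycolysis gene rose, and 2 effector and memory genes rose and 1 fell. At T0, glycolysis (0.933), amino acid and one-carbon genes (0.557), ribosome biogenesis (0.0759), ER stress (0.0725), effector and memory genes (0.463) and apoptosis genes (0.571) were not called either.

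The same cell markers moved with genotype at T6. All 13 B cell markers were higher in KO with a median of 1.31, 10 of them past 0.05 adjusted over the list alone and 0 over all genes, with Ly6d at 1.93 and Cd74 at 1.60 (adjusted p = 5.4e-07; adjusted p = 0.366 with an estimated correlation). All 13 myeloid markers were higher with a median of 0.92 and 1 called, Tyrobp (adjusted p = 2.9e-07; adjusted p = 0.261 with an estimated correlation). All 11 T cell identity genes were lower with a median of -0.27 and Cd3e at -0.94 (adjusted p = 5.0e-07; adjusted p = 0.347 with an estimated correlation). The 3 erythroid markers had a median of 1.92 (adjusted p = 0.058). With a block for replicate number they were called higher (adjusted p = 0.0155, and 0.374 with an estimated correlation and that block). When adjusted over the list alone, 7 myeloid markers and 1 erythroid marker rose and 2 T cell identity genes fell. The 3 CD4 T cell markers were not called as a list in any of the 5 contrasts (lowest adjusted p = 0.572). The 3' minus 5' difference of the Actb control was 0.71 ± 0.09 in KO and 0.50 ± 0.05 in WT at T6 (log2, SD, n = 3, exact permutation p = 0.1, the smallest possible).

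In the T6 comparison 1549 genes had an unadjusted p under 0.05, where chance gives 658. The count of 13 was 8 without WT T0 replicate 1 or KO T0 replicate 2, 6 without WT T0 replicate 2, KO T0 replicate 3 or KO T6 replicate 2, 5 without WT T6 replicate 2 or KO T0 replicate 1, 4 without KO T6 replicate 1 or 3 and 2 without WT T6 replicate 3. With a covariate for composition or for RNA quality 0 genes were called: Insig1 stood at -1.25 (SE 0.15) and -1.11 (SE 0.15) against -1.15 (SE 0.10), Cyp51 at -1.84 (SE 0.28) and -1.50 (SE 0.23) against -1.75 (SE 0.18), so their errors grew, and Tyrobp at 0.96 (SE 0.21) and 1.54 (SE 0.35) against 1.68 (SE 0.25). Median centring gave 3 rises and 20 falls against 4 and 9.

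In WT cells, the change from T0 to T6 gives the activation response of control cells. There 1492 genes rose and 1810 fell, 352 and 599 of them by at least 2-fold. The largest rises were in chemokines and activation genes: Ccl3 by 6.77 (SE 0.28), Ccl4 by 5.72 (SE 0.18), Sema7a by 5.17, Xcl1 by 4.97 and the nuclear receptor Nr4a3 by 4.79. The largest falls were in the complement genes C1qc (-5.11), C1qa (-4.98) and C1qb (-4.65), in Igfbp4 (-5.06) and in the adhesion gene Vcam1 (-4.77). C1qc and C1qa at T6 (5.19 and 6.04) lay near background, so the sizes of their falls depend on the added constant. Of 26 early activation genes 21 rose and 1 fell, with Tnfrsf9, the costimulatory receptor 4-1BB, at 3.88 (median 2.92, adjusted p = 8.6e-23; adjusted p = 0.0676 with an estimated correlation). The counts were the same when adjusted over the list alone.

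In WT, of 20 ribosome biogenesis genes 18 rose, such as Ncl by 0.77 and Pno1 by 1.06 (median 0.76, adjusted p = 1.3e-13; adjusted p = 0.210 with an estimated correlation). Of 15 amino acid and one-carbon genes 12 rose and 1 fell, with Shmt1 at 2.67 and the transporter gene Slc7a5 at 1.72 (median 0.83, adjusted p = 4.6e-09; adjusted p = 0.0676 with an estimated correlation). Of 15 glycolysis genes 6 rose, with hexokinase Hk2 at 2.06, and 2 fell, with the glucose transporter gene Slc2a3 at -0.90 (median 0.35, adjusted p = 0.016; adjusted p = 0.210 with an estimated correlation), and the call was lost with the mean of a gene's probe sets (adjusted p = 0.0946). Of 17 cholesterol synthesis genes 9 rose and 2 fell, with Cyp51 at 2.10, Idi1 at 1.87 and Hmgcs1 at 1.07 (median 0.71, adjusted p = 2.2e-04; adjusted p = 0.362 with an estimated correlation). Of 11 sterol uptake genes 3 rose (Tmem97 by 1.14, Srebf2 by 0.59 and Insig1 by 0.53) and 2 fell, and the list was not called (adjusted p = 0.549). Of 19 fatty acid genes 5 rose, such as Fasn by 1.07, and 5 fell (adjusted p = 0.315). LXR targets fell in 6 of 10 cases and rose in 0, with the cholesterol exporter genes Abca1 at -2.33 and Abcg1 at -1.46 (median -0.74, adjusted p = 4.2e-04; adjusted p = 0.261 with an estimated correlation). Apoe, another of them, fell by 2.26, and macrophage genes such as C1qa (-4.98) fell in the same contrast, so the cell type of these changes is not known. Adjusted over the list alone, rises and falls numbered 20 and 0 for ribosome biogenesis, 13 and 1 for amino acid and one-carbon genes, 7 and 2 for glycolysis, 10 and 2 for cholesterol synthesis, 3 and 3 for sterol uptake, 5 and 5 for fatty acid synthesis and 0 and 7 for LXR targets.

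Naive T cell genes fell in 8 of 16 cases and rose in 1, with Klf4 at -2.06 and Foxo1 at -1.25 (median -0.46, adjusted p = 0.0093; adjusted p = 0.448 with an estimated correlation). Interferon response genes rose in 5 of 17 cases, with the guanylate-binding protein genes Gbp2 at 3.15 and Gbp3 at 2.26 (median 0.41, adjusted p = 6.9e-04; adjusted p = 0.586 with an estimated correlation). Of 17 ER stress genes 5 rose, with Manf at 0.55, and 2 fell, with the chaperone gene Dnajb9 at -1.69 (median 0.34, adjusted p = 0.039; adjusted p = 0.651 with an estimated correlation), and the call was lost without WT T0 replicate 2 (0.104) or WT T6 replicate 1 (0.101), with quantile normalization (0.102) and with the filter at percentile 60 (0.0731). Of 19 effector and memory genes 2 rose and 6 fell, such as Nkg7 by 1.35 (adjusted p = 0.218). Of 12 apoptosis genes 2 rose (Cdkn1a by 2.21 and Bcl2l11 by 1.40) and 2 fell (adjusted p = 0.381). Of 22 cell cycle genes 1 fell, Ccnd3 (adjusted p = 0.417). Adjusted over the list alone, rises and falls were 1 and 11 for naive genes, 5 and 0 for interferon response, 8 and 2 for ER stress, 2 and 6 for effector and memory genes, 3 and 2 for apoptosis and 0 and 0 for cell cycle.

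Myeloid markers fell in 8 of 13 cases in WT and rose in 0, with Tyrobp at -2.90 and Adgre1 at -2.53 (median -1.76, adjusted p = 4.8e-05; adjusted p = 0.366 with an estimated correlation). B cell markers fell in 5 of 13 cases, with Cd74 at -1.73 (median -0.54, adjusted p = 0.040; adjusted p = 0.704 with an estimated correlation), and the call was lost without WT T0 replicate 1 (0.166), WT T6 replicate 2 (0.103), WT T6 replicate 3 (0.0978) or KO T6 replicate 2 (0.0533). T cell identity genes fell in 5 of 11 cases, with Thy1 at -1.33 (median -0.43, adjusted p = 0.031; adjusted p = 0.661 with an estimated correlation), and the call was lost without WT T0 replicate 1 (0.0724), WT T6 replicate 1 (0.0518) or WT T6 replicate 2 (0.0552). Adjusted over the list alone, 1 myeloid marker rose and 9 fell, 5 B cell markers fell, and 1 T cell identity gene rose and 6 fell. Erythroid markers were not called (adjusted p = 0.951). The NK cell list had 1 tested member, Klre1, too few for a set test, at 0.41 and -0.23 in KO against WT at T0 and T6 and at -0.50 on activation in WT. The Actb difference was 0.30 ± 0.08 at T0 and 0.50 ± 0.05 at T6 (log2, SD, n = 3, exact permutation p = 0.1, the smallest possible). Median centring moved the median log2 change of all genes by 0.108 and gave 2051 rises and 1258 falls, and covariates for composition and for RNA quality gave 933 and 1497 genes.

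In KO cells 1372 genes rose and 1374 fell with activation, 356 and 467 of them by at least 2-fold. The largest rises were Ccl3 by 6.11, Ccl4 by 5.24, the cytokine gene Il2 by 5.10 (SE 0.34), Fosl1 by 4.94 and Sema7a by 4.57. The largest falls were C1qc (-5.37), C1qa (-5.22), the mannose receptor gene Mrc1 (-4.78), C1qb (-4.76) and Dtx1 (-4.55). Il2 and Fosl1 at T0 (4.82 and 4.81) and C1qc and C1qa at T6 (5.49 and 6.32) lay near background, so the sizes of their changes depend on the added constant. Of 26 early activation genes 21 rose and 0 fell, with Tnfrsf9 at 3.32 and Nr4a3 at 4.11 (median 2.83, adjusted p = 8.6e-23; adjusted p = 0.0676 with an estimated correlation), and 23 rose and 1 fell when adjusted over the list alone. Between the genotypes 2142 genes were called in both, 2141 of them in the same direction, where independent lists would share 689.

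**Figure D3:**
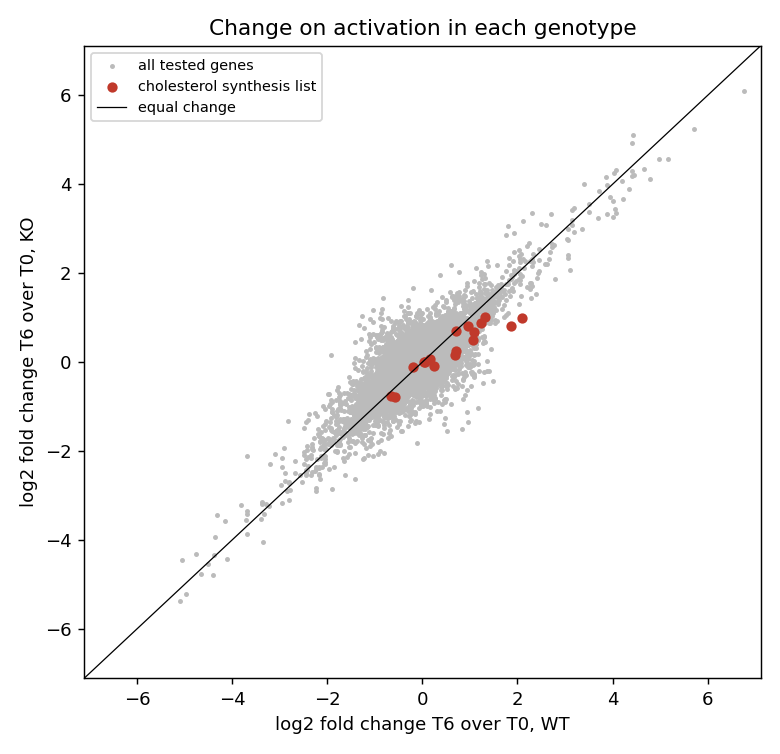
Log2 fold change of T6 over T0 in KO (vertical axis) against that in WT (horizontal axis) for 13156 tested genes. Red points are the 17 cholesterol synthesis genes and the line marks equal change; 16 of the 17 have a lower change in KO than in WT.

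Of 20 ribosome biogenesis genes 18 rose in KO, such as Ncl by 0.70 (median 0.66, adjusted p = 3.5e-11; adjusted p = 0.216 with an estimated correlation). Of 15 amino acid and one-carbon genes 10 rose and 0 fell, with Shmt1 at 2.33 and Psat1 at 1.31 (median 0.89, adjusted p = 2.3e-08; adjusted p = 0.0676 with an estimated correlation). Of 15 glycolysis genes 5 rose, with Hk2 at 1.76, and 1 fell (median 0.33, adjusted p = 0.031; adjusted p = 0.216 with an estimated correlation), and the call was lost with the mean of a gene's probe sets (0.152) and in a separate fit (0.0730). Of 17 cholesterol synthesis genes 7 rose, with Cyp51 at 0.98 and Fdps at 0.88, and 2 fell, with Dhcr7 at -0.79. That list had a median of 0.25 and was not called (adjusted p = 0.053), but was with a block for replicate number (adjusted p = 0.0488; adjusted p = 0.591 with an estimated correlation and that block). Of 11 sterol uptake genes 1 fell, Lpin1 (adjusted p = 0.959). Of 19 fatty acid genes 6 rose, such as Fasn by 0.91, and 4 fell (adjusted p = 0.344). LXR targets fell in 7 of 10 cases, with Apoe at -2.46 and Abca1 at -1.92 (median -0.79, adjusted p = 1.9e-04; adjusted p = 0.240 with an estimated correlation), while macrophage genes such as C1qa (-5.22) fell as well. In KO, adjusted over the list alone, rises and falls numbered 19 and 0 for ribosome biogenesis, 10 and 0 for amino acid and one-carbon genes, 8 and 1 for glycolysis, 8 and 2 for cholesterol synthesis, 0 and 1 for sterol uptake, 6 and 4 for fatty acid synthesis and 0 and 7 for LXR targets.

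Naive T cell genes fell in 7 of 16 cases in KO and rose in 2, with Klf4 at -2.12 (median -0.43, adjusted p = 0.0034; adjusted p = 0.420 with an estimated correlation). Interferon response genes rose in 5 of 17 cases, with Gbp2 at 3.19 and Zbp1 at 1.60 (median 0.64, adjusted p = 2.3e-05; adjusted p = 0.448 with an estimated correlation). Of 17 ER stress genes 3 rose, with Trib3 at 2.11 and Chac1 at 1.88, and 2 fell, with Dnajb9 at -1.32 (adjusted p = 0.417). Of 12 apoptosis genes 4 rose, with Cdkn1a at 2.60, and 2 fell (adjusted p = 0.213). Of 19 effector and memory genes 2 rose, Fasl by 1.57 and Eomes by 0.53, and 3 fell, such as Id2 by 1.43 (adjusted p = 0.173). Of 22 cell cycle genes 0 were called (adjusted p = 0.173; adjusted p = 0.0274 with a block for replicate number; adjusted p = 0.724 with an estimated correlation and that block). In KO, adjusted over the list alone, rises and falls were 2 and 9 for naive genes, 7 and 0 for interferon response, 4 and 3 for ER stress, 4 and 2 for apoptosis, 2 and 3 for effector and memory genes and 0 and 0 for cell cycle.

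Myeloid markers fell in 8 of 13 cases in KO and rose in 1, with Csf1r at -3.94 and Adgre1 at -2.69 (median -1.34, adjusted p = 1.2e-04; adjusted p = 0.405 with an estimated correlation). Of 13 B cell markers 0 were called (median -0.56, adjusted p = 0.113; adjusted p = 0.00158 with a block for replicate number; adjusted p = 0.353 with an estimated correlation and that block). T cell identity genes fell in 6 of 11 cases, with Thy1 at -1.30 and Cd8b1 at -0.83 (median -0.45, adjusted p = 0.0017; adjusted p = 0.564 with an estimated correlation). When adjusted over the list alone, 2 myeloid markers rose and 8 fell, 0 B cell markers passed and 7 T cell identity genes fell. Klre1 fell by 1.14, and erythroid markers were not called (adjusted p = 0.879). The Actb difference was 0.36 ± 0.14 at T0 and 0.71 ± 0.09 at T6 (log2, SD, n = 3, exact permutation p = 0.1, the smallest possible). With a covariate for composition 1338 genes were called, and with one for RNA quality 262.

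The interaction asks whether activation changed a gene differently in KO and WT. By limma 0 genes were called, with 604 at an unadjusted p under 0.05 where chance gives 658, and 1 was called among all probe sets tested separately. The 3 genes with the smallest p were Wscd2 at 1.15, Bace1 at 2.09 and Zc3h13 at -0.77 (adjusted p = 0.522, 0.620 and 0.620). The cholesterol synthesis list was called lower, with 16 of 17 members negative, a median of -0.30 and 3 falls when adjusted over the list alone (adjusted p = 7.0e-07; adjusted p = 0.216 with an estimated correlation). Its members with the smallest p were Cyp51 at -1.12, Idi1 at -1.06 and Hmgcs1 at -0.57. Early activation genes had a median of -0.20, with Nr4a3 at -0.67 (adjusted p = 0.0019; adjusted p = 0.573 with an estimated correlation). Ribosome biogenesis genes had a median of -0.09 (adjusted p = 0.0016; adjusted p = 0.582 with an estimated correlation). Without KO T6 replicate 2 these last calls were lost, with adjusted p = 0.189 for activation genes and 0.174 for ribosome biogenesis, and 1 gene was called without WT T6 replicate 1 or KO T0 replicate 2. The activation gene call was also lost with the mean of a gene's probe sets (0.0881). The other 17 lists were not called (lowest adjusted p = 0.0725). With a block for replicate number, B cell markers (adjusted p = 0.0274), myeloid markers (0.0357) and interferon response (0.0495) were called higher. With an estimated correlation and that block they stood at 0.432, 0.590 and 0.736.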

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

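Apart from the splits of the arrays, the tests of explanations in this part were chosen after the results were seen. For the T cell share the covariate test was chosen after an earlier test of it had been seen.

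The response to activation of 3 lists differed between KO and WT by the test of the interaction: cholesterol synthesis (adjusted p = 6.97e-07), early T cell activation genes (0.00189) and ribosome biogenesis (0.00159). None passed with an estimated correlation, and without KO T6 replicate 2 the early activation genes stood at 0.189 and ribosome biogenesis at 0.174. Among probe sets with no gene name here, 1 was called in KO against WT at T0 and 29 at T6, of which 8 rose and 21 fell.

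The cholesterol synthesis list, lower in KO at T6, kept its call with the RNA quality covariate, at a median of -0.53 (camera adjusted p = 4.6e-10). Over the settings applied to all lists the adjusted p ranged up to this value, apart from fry at 0.000534 and the estimated correlation at 0.0676. The Actb difference was 0.71 ± 0.09 in KO and 0.50 ± 0.05 in WT at T6 (SD, n = 3). That covariate thus differs with genotype, and the fit does not settle whether RNA quality is a cause. Chromosome 9 DNA of another strain cannot be told apart, because 1 of the 17 genes lies on that chromosome, so leaving it out (median -0.55) tests nothing for the other 16. With the T cell identity mean as a covariate, the list stood at -0.85 (bootstrap SE 0.17, camera adjusted p = 2.9e-13). With an estimated correlation the adjusted p was 0.170. When arrays were left out the list stood at -0.71 to -0.92 (camera adjusted p up to 1.1e-09). The identity genes had a median of 0.06 there, which follows from the covariate being their mean. Its slope rests on differences within groups. Among KO T6 arrays, replicate 2 had the lowest identity mean (12.30) and the highest cholesterol list mean (9.35). T cell identity was also lower in KO, so this fit does not decide whether a smaller T cell share is the cause. The identity list includes Cd3e of chromosome 9, so its mean may also carry differences of that chromosome. With the composition covariate the list stood at -0.54 (bootstrap SE 0.19, adjusted p = 0.140 with an estimated correlation). With the erythroid markers as covariate it stood at -0.75 (bootstrap SE 0.16, adjusted p = 0.0138 with an estimated correlation). The identity genes stayed at -0.36 and -0.10 in these fits, so neither fully removed the difference in T cell identity. In the earlier test, within arrays, the list minus T cell identity was lower in KO by 0.36, and the groups overlapped because of KO T6 replicate 2. This had been set down as speaking for a smaller T cell share. Loss of Scap itself, which the design names, stays open: KO against WT compares the genotypes but does not separate Scap from other differences between them.

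The 3 arrays against 3 make 10 splits, too few for a share under 0.05. The size of the cholesterol list median was 0.265 at T0, 0.616 at T6 and 0.303 for the interaction, and the highest of the other splits gave 0.178, 0.435 and 0.246, so 1 of the 10 splits in each case, the real one, was as large. Lists called within the contrast numbered 10 at T0, where 2 splits gave as many (highest other 10), and 9 at T6, where 2 did (highest other 10). For activation they numbered 12 in WT, where 1 did (highest other 8), and 10 in KO, where 4 did (highest other 10). For the interaction there were 3, where 4 splits gave as many (highest other 5).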

How the results depend on the processing

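The chromosome 9, composition and RNA quality alternatives were chosen after the data were seen, as were, for the list tests, leaving out arrays and the settings planned for gene counts alone. Genes called in KO against WT at T0 (5) became 3 with log2(signal + 1), 10 with log2(signal + 64), 2 with no filter, 8 with the filter at percentile 60, 9 with a mean-variance trend, 1 with a separate fit, 0 without chromosome 9 genes, 2 with the RNA quality covariate, and 2 to 9 when arrays were left out. At T6 (13) they became 6 with log2(signal + 1), 8 with quantile normalization, 23 with median centring, 5 with no filter, 33 at percentile 60, 21 with the mean of probe sets, 141 probe sets when all were tested, 29 with the trend, 0 with a separate fit, 24 with the replicate block, 5 without chromosome 9 genes, 0 with either covariate, and 2 to 16 when arrays were left out. Activation in WT (3302) gave 6208 probe sets when all were tested, 933 with the composition and 1497 with the RNA quality covariate, and 2383 to 3527 when arrays were left out. In KO (2746) these were 5578, 1338, 262 and 2012 to 2723. The interaction (0) gave 1 among all probe sets and 0 to 1 when arrays were left out. List calls (43) became 0 with an estimated correlation and 25 with fry, and 41 to 48 when arrays were left out. More tests in the set of all probe sets and fewer arrays or degrees of freedom in the separate fits are part of those settings; for the others the cause was not tested. The covariates share their variation with genotype and time, so lost calls under them do not tell these apart. The direction turned for B cell markers on activation in WT with the composition covariate (median 0.66, adjusted p = 0.0987), which is made from that list, and for interferon response in KO against WT at T6 with the RNA quality covariate (median 0.31, adjusted p = 0.0314; the cause was not tested). Over all alternatives, called list tests kept direction and call in 1000 cases and lost the call in 117. Uncalled ones stayed so in 1284, passed in 73 and changed sign without passing in 119. Of the lost calls, 5 came with chromosome 9 genes left out, 13 with the composition covariate and 2 with the RNA quality covariate. Those are not named list by list here. Called results for genes taken by the naming rule or called between genotypes kept both in 3511 cases and lost the call in 368, and 0 turned. These counts pool the contrasts, activation included, so they do not give the stability of the KO against WT calls. Bace1 at T0 was called in 24 of 24 alternatives, Cyp51 at T6 in 21 of 25, Sc5d in 21 of 24, Insig1 at T6 in 22 of 25 but at T0 in 6 of 25, Tmem108 at T0 in 8 of 24, Idi1 in 6 of 25, Tyrobp in 6 of 25 and Mast4 in 0 of 23. The count of comparisons of array measures (the control ratios and the means of all gene lists, pathways included) whose groups did not overlap was 44, and 44 to 46 under other scalings. Weak signals limit what the arrays can show, since changes near background are compressed by the added constant.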

Other observations

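The macrophage list test was set before its values were seen, as were the splits of the arrays, while the other tests of this part were chosen after the results were seen.

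Further marker lists, written after the data had been seen and sharing 1 gene with the fixed lists, gave more detail on other cell types. In quiescent KO samples all 12 dendritic cell genes were higher than in WT, such as Siglech at 1.45 and Spib at 1.82, with a median of 0.85 (adjusted p = 9.8e-08; adjusted p = 0.0542 with an estimated correlation), and at T6 9 were higher and 3 lower (adjusted p = 2.5e-04; adjusted p = 0.102 with an estimated correlation). Macrophage genes were higher in 15 of 16 cases at T0 and 16 of 16 at T6 (adjusted p = 3.8e-05 and 1.2e-07; adjusted p = 0.155 and 0.0979 with an estimated correlation). All 13 erythroid genes were higher at T0 and at T6, with medians of 1.37 and 1.25 (adjusted p = 1.3e-05 and 2.4e-04; adjusted p = 0.441 and 0.561 with an estimated correlation). B cell genes were higher in 14 of 15 cases at T0 and 15 of 15 at T6 (adjusted p = 5.9e-05 and 9.3e-05; adjusted p = 0.394 in both with an estimated correlation). Plasma cell genes were higher in 7 of 7 cases at both times, with medians of 0.80 and 0.89 (adjusted p = 5.9e-05 and 2.4e-04; adjusted p = 0.342 and 0.356 with an estimated correlation). Neutrophil genes were higher in 8 of 9 cases at both times (adjusted p = 0.042 and 0.104; adjusted p = 0.561 and 0.642 with an estimated correlation). No gene of these lists was called between genotypes.

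Genes of chromosome 9, which carries Scap, were frequent among those that differ by genotype. They made up 18.75% of 112 genes with an unadjusted p under 0.001 in either KO against WT comparison and 5.55% of the other tested genes, a ratio of 3.38 (Fisher's exact p = 1.0e-06), against 0.931 for the activation contrasts. Chromosome 9 DNA of another strain in the KO mice may account for part of these differences. For 13 of the 21 genes taken as a set, a variant under a single probe set is argued against as the whole cause. The mean of a gene's other probe sets, signed by the tested one, had a median of 0.446 (SE 0.124) over these 13. This does not hold for each gene. The other probe sets of Scn2b gave -0.19 and 0.26 against 1.45 on the tested one. That of 9230112J17Rik gave -0.10 against -1.30. Some of the other probe sets lay near background, such as this last one at a mean log2 of 4.56. For 4 of the 13 genes a single other probe set moved the opposite way. Whether a variant adds to the size on the tested probe set was not tested. The rest of the 21 genes gave no value for another probe set, so for them it was not tested at all. By median distance the 21 genes lay no nearer to Scap in gene order than others (one-sided permutation p = 0.729). A median would not show whether some of them lie near Scap. Whether the DNA next to the altered allele is involved therefore cannot be told apart. As first set down, a median distance at or above that of the others (1003 and 840 genes) was to argue against it, and this was relaxed after the value was seen, since the difference is within chance.

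Complement and other macrophage genes fell on activation in both genotypes. On a macrophage list with no gene in the fixed lists, 14 of 16 tested genes fell in WT, and 13 fell and 1 rose in KO, such as Fcna at -3.69 in WT and -3.87 in KO, with medians of -2.31 and -1.91 (adjusted p = 2.7e-10 in both; adjusted p = 0.0542 in both with an estimated correlation). Loss of macrophages between the times may account for this, although the enrichment kit should remove most of them before T0, and lower expression within macrophages is not excluded. Scaling of the arrays is argued against, since it moved the median change of all genes by at most 0.108.

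For counts of genes, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split called 5 genes at T0 (highest other 1), 13 at T6 (highest other 1), 3302 in WT (highest other 1) and 2746 in KO (highest other 2), and 1 of the 10 splits was as large each time. For the interaction it called 0, so all 10 splits gave as many (highest other 2).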
